A study of Mus musculus with 6 samples.

How the data were processed

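Heart RNA of mice 3 months old was measured on 6 one-colour oligonucleotide arrays (Affymetrix). A group of 3 arrays came from desmin-null mice (Des_null) and a group of 3 from desmin-null mice with cardiac overexpression of TNF-α (TNF_Des_null). Groups and replicate numbers were taken from the sample titles. Per the labels, RNA of 3 hearts of each genotype was pooled before labelling, while the series description gives 3 mice per genotype. It is therefore open whether the arrays of a group carry separate animals or repeats of 1 pool, and p-values measure only the spread between these arrays, which may be technical. Per the labels the Des_null mice were of the 129SV strain and the TNF_Des_null mice of a mixed 129SV and C57 background, so strain and transgene cannot be told apart. The labels give no scan date or batch.

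The values deposited by the authors are on the log2 scale, and RMA was used, per the submitters' processing notes, which give no version. The deposited columns did not share 1 distribution: the 99th percentile of the log2 values was 12.27 on Des_null replicate 1, 11.75 and 11.69 on Des_null replicates 2 and 3, and 12.26 to 12.31 on the TNF_Des_null arrays. Whether the quantile normalization step of RMA was run, and over which arrays, is not given in the sources used here. The spread within Des_null (11.69 to 12.27) argues against a step shared by that group or by all arrays. Array medians lay between 5.02 and 5.08. The number of arrays limits the precision.

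The table holds 45101 probe sets, of which 64 are controls. Of the other 45037, 34945 have 1 gene symbol in the platform annotation, 932 have several and 9160 have none; the last 2 kinds name no gene here. Gene identifiers of 34741 probe sets were found in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols and was otherwise used only for the order of genes along chromosomes. Each of 18193 genes was represented by its probe set with the highest mean over the 6 arrays, with no filter on dim probe sets.

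The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Each log2 change is TNF_Des_null minus Des_null. Lists of genes were tested with camera at a preset correlation of 0.01, adjusted over 45 lists. The lists, written from textbook knowledge, held 689 entries, of which 626 were measured; the other entries were not analysed here. The model, the lists, the alternative settings and the rule for named genes were fixed before the data were examined. The rule took Tnf, Des, Krt8 and Krt18, the 10 largest rises and 10 largest falls among genes past the test whose groups did not overlap (provisional names left out, 1 among the falls), and up to 4 members of each list. Members of a list outside the rule, named where a count was small or a group was described, were chosen after their values were seen.

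The fit was tested on simulated data for this comparison of 18193 genes with 50 changed genes per size. It recovered 12% of genes changed by 0.5 on the log2 scale, 74% at 1, 98% at 2 and 100% at 3, and called 5 unchanged genes. Far fewer genes were changed there than the 3869 called in the data, and the simulated noise held no array scale or batch effect. The recovered shares and the number of false calls therefore hold for that setting only. The alternative settings covered an intensity trend, robust hyperparameters, array weights, a replicate block, a filter on dim probe sets, the mean of all probe sets, probe sets open to cross-hybridisation, median centring, quantile normalization, each array left out in turn, treat at 1.2-fold, single probe sets, a Welch test and other set tests. Cyclic loess, Des_null replicates 2 and 3 left out together, and quantile normalization without Des_null replicate 1 were added after seeing the data. The setting called cross-hybridising below left out all probe sets named _a_at, _s_at or _x_at. Those named _a_at are shared by transcripts of the same gene, so for them it only swaps the probe set. Figures were drawn with matplotlib.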

Results

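Desmin is the main intermediate filament protein of heart muscle, and mice without it develop cardiomyopathy. The series asked how cardiac overexpression of the inflammatory cytokine TNF-α changes gene expression in the desmin-null heart, with 3 TNF_Des_null and 3 Des_null arrays of myocardium from mice 3 months old. Published work on these mice concerned ectopic expression of the simple-epithelium keratins Krt8 and Krt18. Of 18193 genes, 3869 (21.3%) differed between the groups, 2768 higher and 1101 lower in TNF_Des_null hearts, and 516 of them differed by at least 2-fold.

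The first principal component held 66.8% of the variance and separated the groups. The second held 19.2% and set Des_null replicate 1 apart. The SD of the log2 difference between Des_null replicates 2 and 3 was 0.157, against 0.336 and 0.341 for each of them and replicate 1, and 0.180 to 0.277 among the TNF_Des_null arrays. Of all genes, 6913 (38.0%) had groups that did not overlap, where chance gives 10%. Each gene named under the fixed rule and past the test was among these. For the 10 largest rises and 10 largest falls the rule required this, so it is no further result for them.

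The 2 engineered genes gave no clear check of the labels. Tnf, which encodes the overexpressed cytokine, stood at 5.87 ± 0.09 in Des_null and 5.94 ± 0.19 in TNF_Des_null hearts (log2, SD, n = 3), a change of 0.07 ± 0.12 (SE) that did not pass the test (limma adjusted p = 0.746). Whether its single probe set lies within the transgene's transcript is not given in the sources used here. Des was 0.39 ± 0.10 higher (adjusted p = 0.0219) on its brighter probe set, and the other probe set gave -0.40 ± 0.13, which did not pass. Quantile normalization ended the Des call (0.22, adjusted p = 0.199), as did leaving out Des_null replicate 2 (0.41), Des_null replicate 3 (0.36), TNF_Des_null replicate 1 (0.41), TNF_Des_null replicate 2 (0.34) or TNF_Des_null replicate 3 (0.42), and the mean of both probe sets was -0.0046. Where these probes lie relative to the deleted part of Des is not known, so they check nothing.

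Krt18 and Krt8, the keratin pair of simple epithelia, were among the 10 largest rises. Krt18 stood at 5.53 ± 0.10 in Des_null and 10.23 ± 0.04 in TNF_Des_null hearts (SD, n = 3), 26.0-fold higher (log2 change 4.70 ± 0.10 SE, adjusted p = 1.58e-07). Krt8 was 12.4-fold higher (3.63 ± 0.14, adjusted p = 3.12e-06) on its brightest probe set, whose Des_null mean of 5.29 lay near the array medians (4.97 on replicate 1), and its other 2 probe sets rose from Des_null means below the median of each array. Of the 7 simple-epithelium keratins 3 rose and 1, Krt19 (-0.67 ± 0.10), fell, also adjusted over the list alone; the median was -0.02 (0.0012 after quantile normalization), the mean 1.15 and the camera sign upward (adjusted p = 0.283, or 0.000851 with fry). Gsta2, a glutathione transferase, rose from 3.94 ± 0.19 to 10.78 ± 0.35 (SD, n = 3; adjusted p = 5.21e-07). Kcne1, a potassium channel subunit, rose 23.9-fold and Myh7, the slow myosin heavy chain, 12.7-fold. The slow skeletal troponin Tnni1 (9.23-fold), the monoamine oxidase Maoa (8.51-fold), the secreted Wnt inhibitor Wif1 (8.47-fold), Rpgrip1 (from 3.88 to 7.30, with a log2 change of 0.95 as the mean of its probe sets) and Plaat1 (from 4.82 to 8.17) completed the set. The Des_null mean of Wif1 (5.35, with 4.97 on replicate 3) lay near the array medians, so its fold is uncertain, as is that of Krt8 (5.29). The table holds no detection calls, and the Des_null levels of Gsta2, Rpgrip1 and Plaat1 lay below the median of each array and are not shown to be above background, so their folds and their order are not given.

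Mmp12, the macrophage metalloelastase, fell from 10.45 ± 0.31 to 4.55 ± 0.20 (SD, n = 3; adjusted p = 6.23e-07), and since the latter lies below each array's median and is not shown to be above background, no fold is given. Myot, which encodes the Z-disc protein myotilin, was 21.3-fold lower and Gpnmb, a glycoprotein of lysosome-rich macrophages, 15.3-fold lower on its brightest probe set (log2 change -3.93, or -1.94 as the mean of its probe sets). Rpl3l, a ribosomal protein of striated muscle, was 8.98-fold lower and the integrin Itgax 6.84-fold lower. The TNF_Des_null means of Myot (5.37) and Itgax (5.26, with 4.99 on replicate 1) lay near the array medians, so their folds are uncertain. Cyfip2 (-2.36, or -1.34 as the mean of its probe sets), the apelin receptor Aplnr (-2.32, or -1.51 as that mean and -0.69 with its _a_at probe set left out) and Wnk2 (-2.13, or -0.80 as the mean) were also in the set, with Gpr22, whose TNF_Des_null level of 4.97 is also below the median of each array. Pik3cd was also in this set with -2.44 ± 0.73, but its Des_null SD was 1.81. Des_null replicate 1 (8.49) lay beside the highest TNF_Des_null array (8.47), and the call ended under quantile normalization (adjusted p = 0.0523), with robust hyperparameters (0.0752) and without Des_null replicate 2, Des_null replicate 3 or any TNF_Des_null array (adjusted p up to 0.154).

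**Figure D1:**
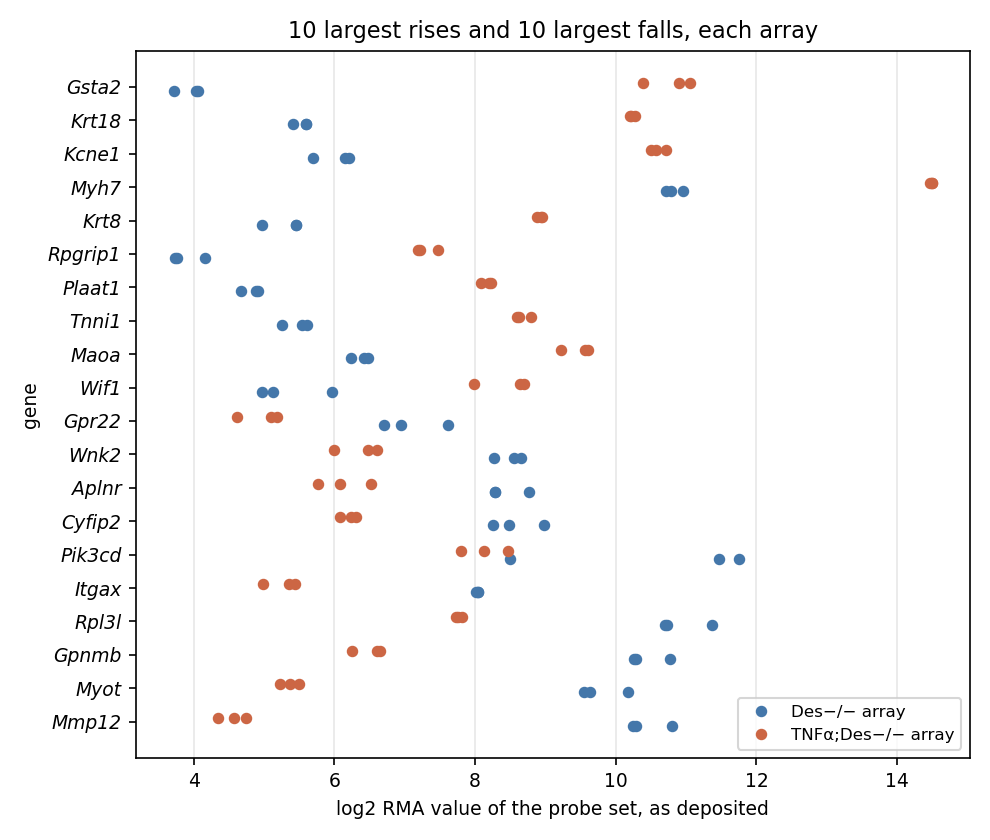
Deposited log2 RMA values (horizontal axis) of the 10 genes with the largest rise and the 10 with the largest fall (vertical axis), with 1 point per array and 3 arrays per group. As the rule of choice required, the groups do not overlap for any of the 20 genes. Mmp12 falls from 10.45 to 4.55 on average, and Pik3cd rests on Des_null replicates 2 and 3.

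The balance of rises and falls depended on the scaling of arrays. As deposited, 71.5% of the genes past the test were higher in TNF_Des_null hearts, and 53.6% after quantile normalization, which forces the arrays onto 1 distribution and called 4085 genes (2189 higher, 1896 lower). In both, 2090 genes were higher and 1093 lower, and 0 had opposite signs; 385 genes differed by at least 2-fold in both, 226 higher and 159 lower. The median log2 change of the brightest 3639 genes was 0.27 as deposited and 0.02 after quantile normalization. Fewer or more genes passed when 1 array was left out: 5814 without Des_null replicate 1, 2232 without Des_null replicate 2, 2220 without Des_null replicate 3, 2075 without TNF_Des_null replicate 1 and 2068 without TNF_Des_null replicate 3. Technical measures also moved with the group: the log2 ratio of 3' to 5' probe sets was 0.32 ± 0.04 for Gapdh in TNF_Des_null and -0.01 ± 0.03 in Des_null (SD, n = 3), and 0.73 ± 0.10 against 0.48 ± 0.08 for Actb.

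**Figure D2:**
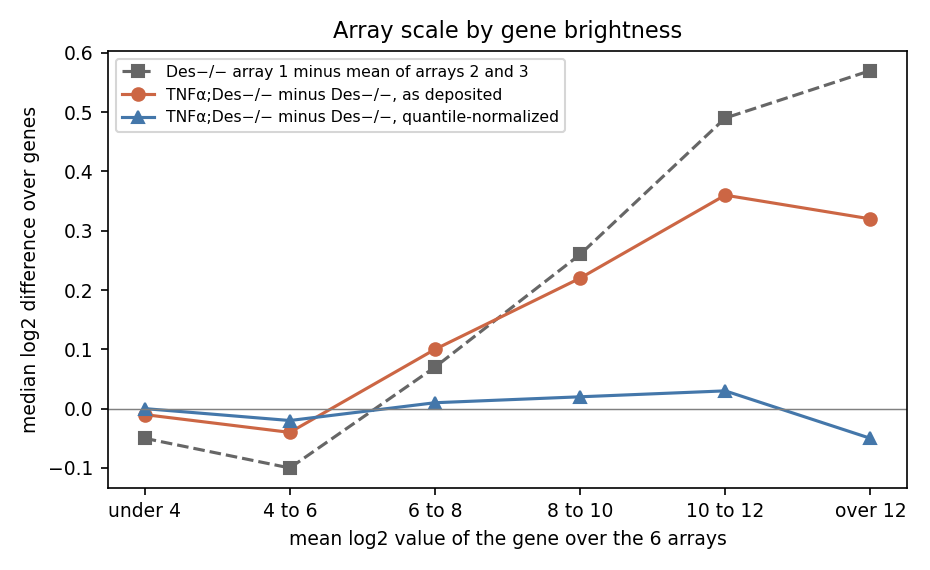
Median log2 difference over genes (vertical axis) by the mean log2 value of the gene over the 6 arrays (horizontal axis). The difference between groups as deposited rises with brightness to 0.36, as does that between Des_null replicate 1 and the other 2 Des_null arrays (to 0.57), while after quantile normalization it stays between -0.05 and 0.03.

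Of the 45 gene lists, 9 were shifted by camera, 5 higher and 4 lower, and the same 9 were called after quantile normalization together with 5 lower lists. These 5 were fatty acid oxidation, oxidative phosphorylation, the citric acid cycle, MHC class II antigen presentation and smooth muscle and pericytes. The MHC class II median was -0.35 (camera adjusted p = 0.00204), and -0.11 (0.152) as deposited. For smooth muscle and pericytes it was -0.39 (0.0231), and -0.06 (0.283) as deposited. None of the 9 held with a correlation estimated from the data, where 0 lists passed; fry called 17. Without Des_null replicate 1, 17 lists were called.

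Fetal and stress genes of the heart were higher as a list, with 8 of 11 measured members up and 1 down (median log2 change 1.14, camera adjusted p = 3.67e-05), and 8 up and 2 down after quantile normalization (median 0.71). The adjusted p = 0.975 with an estimated correlation. Beside Myh7 and Tnni1, the natriuretic peptide genes Nppb (2.15 ± 0.13 SE) and Nppa (0.93 ± 0.16; adjusted p = 0.0607 with an intensity trend) rose, as did the smooth muscle actin Acta2 (1.89 ± 0.14, or 1.02 as the mean of its probe sets and 0.80 with cross-hybridising ones left out). Nppa rose by 0.43 after quantile normalization, and its TNF_Des_null mean of 15.03 lies at the top of those arrays, whose highest values were 15.012 to 15.044. The skeletal actin Acta1 fell by 1.35 on the log2 scale. Adjusted over the list alone, 9 rose and 2 fell. The probe sets of the adult myosin Myh6 disagreed. The brighter gave 0.40 ± 0.18, which did not pass, while the other fell by 2.71 on the log2 scale (limma adjusted p = 0.000944 over all probe sets). The brighter lay near the top of the arrays, so it may not register a change. It read 14.16 and 14.19 on Des_null replicates 2 and 3, whose highest values were 14.199 and 14.226.

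Of 19 genes of muscle intermediate filaments and the Z-disc, 6 rose and 1, Myot, fell (8 and 1 adjusted over the list alone; median 0.36), while 4 rose and 3 fell after quantile normalization (6 and 6 over the list alone; median 0.03; as deposited, camera adjusted p = 0.152, or 0.00309 at a median of 0.49 without Des_null replicate 1). The intermediate filament genes Synm and Sync rose by 1.03 ± 0.21 and 0.90 ± 0.10 (SE; Sync 0.51 as the mean of its probe sets), and the Synm call was lost without TNF_Des_null replicate 3 (adjusted p = 0.0527). Of 16 genes of the desmosome and intercalated disc, 5 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.33), and 2 rose and 1 fell after quantile normalization (4 and 2 over the list alone; median 0.10; as deposited, camera adjusted p = 0.199, or 0.00908 at 0.46 without Des_null replicate 1). The intercalated disc genes Ctnna1 (0.74 ± 0.13) and Xirp1 (0.69 ± 0.12) rose under both scalings (0.35 and 0.44 after quantile normalization), though the mean of all probe sets of Ctnna1 did not pass (0.42, adjusted p = 0.0693), and the Des call ended after quantile normalization. Among 17 genes of calcium handling and excitation, 4 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.13), while 3 rose and 6 fell after quantile normalization (3 and 7 over the list alone; median -0.13; as deposited, camera adjusted p = 0.826). The potassium channel partner Kcnip2 rose by 1.51 ± 0.10 (0.93 as the mean of its probe sets) and the calcium-binding Hrc fell by 1.06 on the log2 scale.

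Oxidant and protein stress genes rose together. Of 20 measured antioxidant genes, 15 rose and 0 fell (median 1.0, camera adjusted p = 1.43e-09), 16 adjusted over the list alone. The adjusted p = 0.908 with an estimated correlation. Thioredoxin reductase Txnrd1 rose by 2.68 ± 0.10 (SE; 0.96 as the mean of its probe sets), the quinone reductase Nqo1 by 2.56 ± 0.10 and sulfiredoxin Srxn1 by 2.34 ± 0.11. Genes of the unfolded protein response, which handle misfolded protein in the endoplasmic reticulum, rose in 16 of 20 cases (median 0.74, camera adjusted p = 2.33e-07), 18 adjusted over the list alone. The adjusted p = 0.908 with an estimated correlation. Chac1 rose by 1.91 ± 0.10 and Creld2 by 1.60 ± 0.11, while Atf3 was the 1 member that fell (-0.49 ± 0.12), a call lost without Des_null replicate 3 or TNF_Des_null replicate 1 (adjusted p up to 0.0824).

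Heat shock and chaperone genes rose in 11 of 17 cases with 0 falls (median 0.74, camera adjusted p = 2.33e-07), 16 adjusted over the list alone. The adjusted p = 0.975 with an estimated correlation. Hsp90aa1 rose by 1.80 ± 0.19 (SE; 1.10 as the mean of its probe sets) and Hsph1 by 1.38 ± 0.13. Genes of the proteasome and muscle ubiquitin ligases rose in 7 of 14 cases with 0 falls (median 0.53, camera adjusted p = 0.00571), and 9 rose and 1 fell adjusted over the list alone. The adjusted p = 0.986 with an estimated correlation, 0.0641 with the filter on dim probe sets, 0.112 with fry and 0.457 (median 0.19) without Des_null replicates 2 and 3. The autophagy receptor Sqstm1 rose by 0.94 ± 0.15 and the proteasome subunit Psma5 by 0.89 ± 0.17 (0.57 and 0.58 after quantile normalization). Both rest on _a_at probe sets. With these swapped for other probe sets of the same genes neither passed, at 0.07 (limma adjusted p = 0.689) and 0.06 (adjusted p = 0.724), so their probe sets disagree. After quantile normalization the medians of these lists were 0.75 for antioxidant, 0.55 for unfolded protein, 0.46 for heat shock and 0.17 for proteasome genes.

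**Figure D3:**
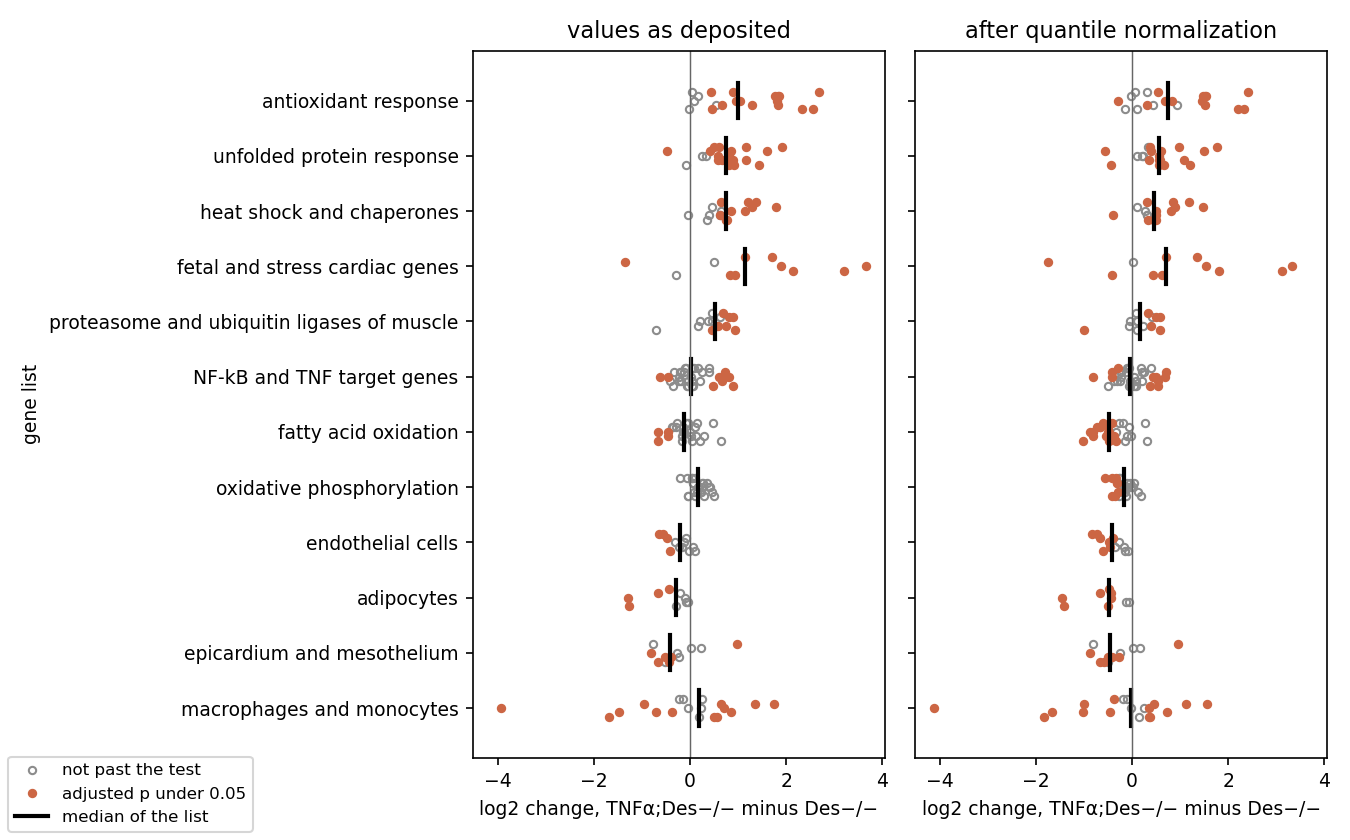
Log2 change between groups (horizontal axis) of each measured member of 12 gene lists (vertical axis) as deposited and after quantile normalization; filled points passed the test and bars mark list medians. The antioxidant median is 1.0 and 0.75, while that of oxidative phosphorylation turns from 0.16 to -0.17.

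Target genes of NF-κB and TNF were not called by camera but were called higher by fry (adjusted p = 0.0467). Of 34 measured, 7 rose and 2 fell, both over all genes and adjusted over the list alone (median 0.03, or -0.05 with 7 rises and 4 falls after quantile normalization; camera adjusted p = 0.993, with a downward sign against a mean of 0.09). The inhibitor Nfkbia rose by 0.90 ± 0.10 (SE; 0.54 after quantile normalization) and Nfkb2 by 0.82 ± 0.11, while Irf1 fell by 0.63 on the log2 scale. The chemokine Ccl2 stood at -0.23 ± 0.12, Il6 at -0.04 ± 0.10 and the adhesion gene Vcam1 at 0.03 ± 0.16, and none of these passed, though Ccl2 did with array weights (-0.38, adjusted p = 0.0122). Interferon-stimulated genes rose in 7 and fell in 3 of 22 cases (7 and 4 adjusted over the list alone; camera adjusted p = 0.656, fry 0.0467), with Ifit1 at 1.46 ± 0.14 and Xaf1 at -0.86 ± 0.14 (-0.26, adjusted p = 0.055 for the mean of its probe sets). Of 23 apoptosis and death receptor genes, 7 rose and 1 fell (9 and 2 adjusted over the list alone, and 5 and 2 after quantile normalization; camera adjusted p = 0.0902, or 0.0309 with cross-hybridising probe sets left out; fry 0.0137). The TWEAK receptor Tnfrsf12a rose by 1.41 ± 0.11 and the survival gene Bcl2 by 1.32 ± 0.10, and the pro-apoptotic Bcl2l11 fell by 1.08 on the log2 scale (0.87 and -0.65 as the means of their probe sets).

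Matrix genes moved both ways. Of 24 genes of fibrillar matrix and fibrosis, 9 rose and 5 fell (10 and 5 adjusted over the list alone; median 0.16, camera adjusted p = 0.668), and after quantile normalization 6 rose and 9 fell. The growth factor Tgfb2 rose by 1.73 ± 0.14 (SE), and fibronectin Fn1 and periostin Postn fell by 1.38 and 1.0 on the log2 scale (Fn1 -0.88 as the mean of its probe sets). Of 13 metalloproteinase and inhibitor genes, 3 rose, among them Mmp14 (1.12 ± 0.16, or 0.61 as the mean of its probe sets) and Mmp3 (0.66 ± 0.12), and Mmp12 fell (3 and 3 adjusted over the list alone), while 3 rose and 4 fell after quantile normalization (median -0.01). As deposited the median of that list was 0.07, its mean -0.34 and its camera sign downward (adjusted p = 0.826, or 0.0467 with fry).

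Genes of energy metabolism depended on the scaling of arrays. Of 25 genes of fatty acid oxidation, 4 fell and 0 rose as deposited (median -0.13, camera adjusted p = 0.0537; 3 fell adjusted over the list alone), and 16 fell after quantile normalization (median -0.48, camera adjusted p = 3.33e-08). The latter gave an adjusted p = 0.0989 with an estimated correlation. As deposited, the list was also called without Des_null replicate 2 (0.00482), Des_null replicate 3 (0.00379) or TNF_Des_null replicate 1 (0.0458), but without Des_null replicate 1 the median was 0.01 (0.84), and 0.01 (0.611) with array weights. It was called with the filter on dim probe sets (0.0144) and with the mean of all probe sets (0.0242). Among the 4 were Acaa2 (-0.67 ± 0.12 SE; -1.03 after quantile normalization) and Angptl4 (-0.67 ± 0.10), and the latter turned to 0.12 (adjusted p = 0.531) with cross-hybridising probe sets left out. Of 25 genes of oxidative phosphorylation, 0 passed as deposited, also adjusted over the list alone (median 0.16). After quantile normalization 8 fell (median -0.17) and camera called the list lower (adjusted p = 0.00139, or 0.297 with an estimated correlation). Of 15 genes of the citric acid cycle 0 passed as deposited, also adjusted over the list alone (median 0.18). After quantile normalization 4 fell (median -0.20), and this list was also called lower (camera adjusted p = 0.00102, or 0.439 with an estimated correlation). Both lists were called higher without Des_null replicate 1, at 0.36 (adjusted p = 0.000162) and 0.28 (0.00819), and with array weights, at 0.32 (0.00476) and 0.26 (0.0328), so their direction is not settled. Glucose uptake and glycolysis genes Slc2a1 (1.14 ± 0.17) and Hk1 (1.13 ± 0.11) rose; 5 of 14 rose as deposited (5 and 1 fall adjusted over the list alone; median 0.30, or -0.08 after quantile normalization; camera adjusted p = 0.284, or 0.0312 at 0.49 without Des_null replicate 1), and 4 rose and 5 fell after quantile normalization.

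Among cell types, 4 marker lists were lower as deposited, and smooth muscle and pericytes were called lower only after quantile normalization or under other alternatives. Of 12 endothelial markers 4 fell and 0 rose, also adjusted over the list alone (median -0.20, camera adjusted p = 0.00571), among them Egfl7 (-0.65 ± 0.11 SE) and Tie1 (-0.57 ± 0.12), and 7 fell after quantile normalization (9 over the list alone; median -0.43). The adjusted p = 0.975 with an estimated correlation, 0.106 with fry and 0.145 (median -0.14) with cross-hybridising probe sets left out. Of 12 markers of epicardium and mesothelium 5 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.41, camera adjusted p = 0.00413), including the keratin Krt19 (-0.67 ± 0.10). The adjusted p = 0.975 with an estimated correlation. Of 9 adipocyte markers 4 fell and 0 rose (5 adjusted over the list alone; median -0.30, or -0.48 with 7 falls after quantile normalization; camera adjusted p = 0.000468), among them Ucp1 (-1.30 ± 0.12) and Adipoq (-1.27 ± 0.19). The adjusted p = 0.908 with an estimated correlation. Of 12 skeletal muscle markers 3 fell, also adjusted over the list alone, among them Casq1 (-1.58 ± 0.11) and Tnnt3 (-0.40 ± 0.11; median -0.19, camera adjusted p = 0.0114, or 0.0574 at -0.11 without TNF_Des_null replicate 3 and 0.121 without Des_null replicates 2 and 3). The adjusted p = 0.908 with an estimated correlation. The Tnnt3 call was lost without Des_null replicate 2, Des_null replicate 3, TNF_Des_null replicate 1 or TNF_Des_null replicate 3 (adjusted p up to 0.145). Of 14 cardiomyocyte markers 0 passed (median 0.35, or -0.09 after quantile normalization), but the list was called higher without Des_null replicate 1 (0.55, adjusted p = 3.8e-05) and with array weights (0.52, 0.00155), and lower with cyclic loess (-0.14, 0.022). Of 12 fibroblast markers 4 rose as deposited, also adjusted over the list alone (median 0.21, camera adjusted p = 0.224), while 2 rose and 4 fell after quantile normalization (median -0.05), and the list was called higher without Des_null replicate 1 (0.38, adjusted p = 0.00908).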

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

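Among the tests in this part, those of the keratins, of the hybridisation controls and of other splits of the arrays were chosen after the result was seen. The chromosome tests were first worded for genes at least 2-fold apart and reworded, before they were run, for all genes past the test; both sets are given because they gave different answers.

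The bacterial control transcripts, which are added to each labelled sample and no mouse gene can change, differed between the groups. The log2 ratio of BioC to the mean of BioB, BioD and Cre was -1.26 ± 0.08 in Des_null and -2.90 ± 0.08 in TNF_Des_null arrays (SD, n = 3), a difference of -1.64. The other probe set of Myh6, which the comparison of genes did not use, fell by 2.71 on the log2 scale. Of the probe sets that name no gene or several, 107 passed the test and were at least 2-fold apart, 60 of them higher in TNF_Des_null hearts.

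Krt8 and Krt18 were 12.4-fold and 26.0-fold higher, the former an uncertain fold since its Des_null mean of 5.29 lay near the array medians. Cells of the epicardium or mesothelium would carry their other markers, but the median log2 change of 11 such markers without keratins was -0.39 (95% bootstrap range -0.53 to 0.01), and the brightest stood at 8.04 in Des_null and 7.60 in TNF_Des_null hearts. For 14 markers of lung and airway epithelium it was 0.04 (-0.06 to 0.09), with the brightest at 7.53 and 7.28. The smallest measured change over all 4 probe sets was 3.15, so the rise of Krt8 does not rest on 1 aberrant probe set of its 3. The brightest of these 3 (_a_at) is of the kind shared by transcripts of the same gene. The others (_x_at) are open to cross-hybridisation, which this test cannot exclude. Krt18 has only 1 probe set, which is not of those kinds, so an aberrant one cannot be excluded for it. Expression in heart muscle cells under TNF-α is a hypothesis that was not tested, and strain and separate hybridisation stay open because they coincide with genotype.

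More genes were higher than lower as deposited (71.5%). Against Des_null replicate 1 alone, whose bright end matched the TNF_Des_null arrays, 55.6% were higher, as array scale would give, while median centring left 74.5%. The single Des_null array is assumed to vary like the TNF_Des_null arrays, and since it also differed from its group in single genes (66 after quantile normalization) the comparison does not isolate scale, so a broad rise in TNF_Des_null hearts stays open beside it. The control ratio difference of -1.64 shows that control transcripts or hybridisations differed between the groups. Since no array of either group shares the other's control ratio, hybridisation and genotype cannot be told apart for any gene, and no within-batch value can be had.

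A total of 3869 genes passed the test between groups of unlike strain background, and of 6 measured genes reported to vary between mouse strains 3 were higher and 1 lower (camera adjusted p = 0.351, fry 0.0137). Both groups should carry 129SV sequence around the targeted Des gene, so local strain variants would leave few called genes there. Yet 17.0% of the 100 tested genes nearest to Des passed (exact 95% interval 10.2 to 25.8) against 21.3% elsewhere (2-sided Fisher exact p = 0.329). That argues against local variants behind nearly all calls. The lower bound of 10.2% still allows them a large part, and variants acting on distant genes would not show in this test. For genes at least 2-fold apart the shares were 3.0% (0.6 to 8.5) and 2.8%, too few to decide. Neighbouring genes called in the same direction were 1.09 times as frequent as in 10000 shuffles for all called genes (549 pairs against 501), which is short of the 1.5 set beforehand yet above the shuffled range of 464 to 539. For genes at least 2-fold apart the ratio was 1.62 (14 pairs against 8.64, shuffled range 3 to 15, one-sided permutation p = 0.0534; 1.73 before the related pair Mt1 and Mt2 was removed by a corrected family filter), past that mark, so strain blocks may contribute to the larger changes, as may ordinary co-regulation of neighbours.

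The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 3869 genes (highest other 0) and 516 genes at least 2-fold apart (highest other 0), each as large in 1 split, the real one itself. With limma, the other splits called 0 genes, and at an unadjusted p under 0.05 up to 3089, against 6243 for the real split. Each other split mixes the groups, so the group difference enters its spread and low gene counts were all but set in advance. These gene counts therefore decide nothing. The real split gave 9 shifted lists, and 4 of the 10 splits, the real one included, gave as many. The highest other was 21. The splits with 16, 19 and 21 lists put Des_null replicate 1 with 2 TNF_Des_null arrays; after quantile normalization they gave 2, 3 and 0 lists, so these counts depended on the scaling of arrays, while the real split gave 14 (highest other 5).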

How the results depend on the processing

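Cyclic loess, the fit without Des_null replicates 2 and 3, and quantile normalization without Des_null replicate 1 were chosen after seeing the data. Of 124 named genes 74, and of 45 lists 15, kept their direction and side of the threshold under each alternative that gave them a value per gene or list; leaving out cross-hybridising probe sets did so for 103 of these genes, and the filter on dim probe sets for 115 and for 42 lists. Of the 112 named genes past the test, 82 also passed treat, 28 the Welch test, and 110 quantile normalization without Des_null replicate 1. Without Des_null replicates 2 and 3, which leaves 1 Des_null array that is assumed to vary like the others, 28 named genes lost their call, among them Nppa (0.54), Synm (0.55), Ctnna1 (0.47), Xirp1 (0.48), Slc2a1 (0.78), Psma5 (0.54), Krt19 (-0.65) and S100a9 (0.49), as did Ctsd (0.54). With no detection calls, levels below the array medians are not shown to be above background. Genes at least 2-fold apart stayed between 352 and 693. The count of 3869 genes moved to 8414 with array weights, which gave Des_null replicate 1 a weight of 0.23, to 1587 without Des_null replicates 2 and 3, to 1222 with treat, and to 373 with a Welch test; 6695 single probe sets passed. Leaving out 1 array gave 2068 to 5814 genes, 8 to 17 lists and a Des change of 0.34 to 0.42. Shifted lists went from 9 to 15 with array weights, 14 with quantile normalization, 15 with cyclic loess, 17 with fry and 0 with an estimated correlation. The share higher moved from 71.5% to 53.6% with quantile normalization, 51.8% with cyclic loess, 55.6% without Des_null replicates 2 and 3, and 48.8% with quantile normalization and no Des_null replicate 1. Des lost its call at 0.22 (quantile), 0.19 (cyclic loess) and 0.36 (without Des_null replicates 2 and 3), and turned to -0.0046 with the mean of both probe sets, which point in opposite directions. Signs turned for Ighm (-0.08 with the mean of all probe sets, -0.02 without cross-hybridising ones), and, without cross-hybridising probe sets, for Angptl4 (0.12), Idh3a (-0.37) and Ager (-0.14). Oxidative phosphorylation turned to -0.17 (quantile), -0.25 (cyclic loess) and -0.17 (without Des_null replicates 2 and 3), the citric acid cycle to -0.20, -0.22 and -0.15, and cardiomyocytes to -0.14 (cyclic loess). In contrast, camera called these lists higher without Des_null replicate 1 (0.36, 0.28 and 0.55 in that order) and with array weights (0.32, 0.26 and 0.52). NF-κB targets (0.03) are called higher with fry (adjusted p = 0.0467) and have a downward sign with camera. Apart from scale and probe set choice, the cause was not tested.

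With a replicate block 4278 genes passed, 531 of them at least 2-fold apart, and 9 lists. Deviations of arrays with the same number correlated at 0.25, 0.31 and -0.27, and not every array correlated best with its own number. In each group a single array opposed the others, Des_null replicate 1 at -0.85 and TNF_Des_null replicate 2 at -0.66 and -0.72. These correlations therefore cannot tell whether the numbers pair the arrays.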

Other observations

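In this part, the description of arrays that stand apart was chosen after the values were seen, as were the genes named there; the tests of the 3 added lists were set before their medians were seen, after Ctsk and Acp5 of the macrophage list had been, and the median without these 2 was added later.

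Macrophage genes split in opposite directions. Of 19 measured markers of macrophages and monocytes, 7 rose and 6 fell, also adjusted over the list alone (median 0.18 as deposited and -0.03 after quantile normalization, mean -0.13, camera adjusted p = 0.668 with a downward sign). The lipopolysaccharide receptor Cd14 rose by 1.75 ± 0.10 (SE) and Lyve1, a marker of resident macrophages, by 1.35 ± 0.20. Beside Gpnmb, the perforin-like Mpeg1 fell by 1.69 on the log2 scale, Cd68 by 1.48 and Lgals3 by 0.72. The complement gene C1qa rose by 0.91 ± 0.14 (0.60 after quantile normalization), and the receptor C3ar1 fell by 1.83 on the log2 scale.

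Clock genes also moved both ways. Of 15, 4 rose and 3 fell (median 0.03, camera adjusted p = 0.989), also adjusted over the list alone, with Ciart at 1.41 ± 0.10 (SE), Nr1d1 at 1.19 ± 0.16 and Per1 at 0.93 ± 0.10 against Hlf at -1.96 ± 0.23 and Per2 at -0.45 ± 0.10. The Per2 call was lost without Des_null replicate 2 or TNF_Des_null replicate 1 (adjusted p up to 0.061). Of 12 immediate early genes 5 rose, among them Ccn1 (1.54 ± 0.13, or 0.80 with cross-hybridising probe sets left out), Nr4a1 (0.72 ± 0.09) and Egr1 (0.67 ± 0.11), and Atf3 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.224, fry 0.0467). Time of collection is not given in the labels. Of 9 neutrophil markers 2 rose and 0 fell (median 0.0025, camera adjusted p = 0.952): S100a8 (0.86 ± 0.09) and S100a9 (0.54 ± 0.10), whose Des_null levels of 4.23 and 4.35 lay below the array medians and are not shown to be above background. The neuronal hydrolase gene Uchl1 rose by 2.37 ± 0.10. Of 6 measured genes listed as varying between mouse strains 3 rose and 1 fell (camera adjusted p = 0.351, fry 0.0137), with Wdfy1 at 1.09 ± 0.10 (0.64 as the mean of its probe sets) and Ifi202b at -0.98 ± 0.18.

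Des_null replicate 1 differed from the other Des_null arrays in single genes as well as in scale. Which of the Des_null arrays are the unusual ones is not settled. Replicate 1 lay more than 1 log2 unit from both other Des_null arrays, themselves within 0.5 of each other, for 125 genes (66 after quantile normalization), against 0 to 12 genes for each other array. Of 60 such genes under both scalings, 55 were nearer to the TNF_Des_null mean than to the other Des_null arrays. A small shift of the TNF_Des_null arrays toward replicate 1 is enough for this count. It includes Sesn3, at 9.04 on replicate 1, 7.30 and 7.46 on the other Des_null arrays and 7.44 to 7.81 in TNF_Des_null. Cryl1 read 6.54 on Des_null replicate 1, 11.67 and 11.58 on the other Des_null arrays and 5.95 to 6.73 in TNF_Des_null. E2f5 read 7.98 against 11.49 and 11.65, with 7.60 to 8.05 in TNF_Des_null. The nuclear RNA Malat1 read 11.87 against 9.96 and 10.02, with 11.67 to 11.72 in TNF_Des_null. For these 3 genes Des_null replicates 2 and 3 stood apart from all other arrays. The 3' probe set of the 18S ribosomal RNA control ranged from 5.875 to 9.554 over the 6 arrays.

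The rise of unfolded protein genes raised the hypothesis that the amino acid branch governed by ATF4 moved too. In a list of 19 measured genes that shares none with the first, 11 rose and 0 fell (median 0.46, camera adjusted p = 0.0013 over the 3 added lists; 0.40 and 0.00361 after quantile normalization). The adjusted p = 0.239 with an estimated correlation. Aldh18a1 rose by 1.48 ± 0.17 (SE), Psat1 by 1.23 ± 0.12 and Mthfd2 by 0.99 ± 0.12, while Phgdh (0.12 ± 0.18) passed only as the mean of its probe sets (0.49, adjusted p = 0.0253), so the data are consistent with a partial engagement of that branch.

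For the antioxidant genes, the hypothesis that genes of NADPH production and the pentose phosphate pathway moved too was left open. Of 7 measured genes 2 rose, among them Taldo1 (1.61 ± 0.11 SE) of the pentose phosphate pathway, which does not itself make NADPH. The NADPH-producing Me1 (0.37 ± 0.13, limma adjusted p = 0.088) and Idh1 (0.38 ± 0.13, 0.066) did not pass. The median of 0.37 (camera adjusted p = 0.0963) went to 0.07 after quantile normalization, with a bootstrap range of -0.20 to 0.16. For Mmp12 and Gpnmb, the hypothesis of fewer or less active lysosome-rich macrophages was left open. Of 10 measured genes of that type 5 fell and 2 rose (median -0.40, camera adjusted p = 0.0388, and -0.64 and 0.0129 after quantile normalization), among them Acp5 (-1.26 ± 0.12) and Ctsk (-1.21 ± 0.10), against rises of Ctsd (0.81 ± 0.13, or 0.43 after quantile normalization) and Syngr1 (1.27 ± 0.14, or -0.22 with cross-hybridising probe sets left out). The adjusted p = 0.455 with an estimated correlation, and the bootstrap range of the median, -0.83 to 0.40, includes 0. Without Acp5 and Ctsk, which had been seen to fall, the median was -0.19 (camera adjusted p = 0.486, and -0.34 and 0.245 after quantile normalization).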
